A study of Mus musculus with 3 samples.

How the data were processed

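Total RNA of mouse BMDCs was labelled with the Hy3 dye of the Exiqon miRCURY power labelling kit and hybridised to miRNA capture arrays, per the labels' protocols. The arrays were read with a GenePix 4000B scanner and GenePix Pro 6, per the series' design text. The labels give 3 samples, namely a control, a co-culture with ID8 cells and a co-culture with CT-26 cells, each on 1 array. The culture of the control sample is described no further in the sources used here. The deposited table spells the ovarian line 1D8 and the labels spell it ID8; the columns were taken as 1 line because the normalized values equal those of the ID8 sample in the series matrix.

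The deposited table holds 3 kinds of intensity for each of 1408 probes: raw intensity, corrected intensity and normalized intensity, per the file headers. All raw and corrected values are multiples of 0.25, as a mean of 4 spots would give, though averaging is not stated. Raw minus corrected intensity was a local background between 46 and 73.75 units over all probes. Within each array, the deposited corrected intensity divided by the deposited normalized intensity was a constant, 325 for the control, 398.25 for ID8 and 335.25 for CT-26. That constant equals the median corrected intensity of the 159 mouse probes at or above 50 on all 3 arrays, a rule found from the values and not given in the sources used here. The series matrix holds the same normalized intensities, with a largest difference of 0. Its scale is therefore linear and its centring the constant above. No genome build is named in the files, so no coordinates are printed.

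Probes fall into 579 with a mouse name (568 distinct names, 10 of them with more than 1 probe), 660 with no name, 78 spike-in probes, 40 Hy3 marker spots, 21 empty spots, 10 viral probes, 10 small nucleolar RNA probes, 8 negative probes and 2 U6 probes. The miRNA names are those of the table. For 548 of the 568 names a gene was found in the RefSeq gene table of assembly GRCm38.p6, which served only to tell which miRNA genes neighbour each other, within 1000 bp. For miR-138, let-7d, let-7f and let-7g the probes disagreed, with 1 probe above the floor and the other near 0, while both let-7i probes were above the floor on both co-culture arrays. Members of the let-7 family, miR-17 with miR-20a, and miR-103 with miR-107 differ by few bases, so their probes may share signal and their values are uncertain to that extent.

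Ratios were taken from the authors' normalized intensity as deposited, on the log2 scale. A miRNA entered a ratio when its corrected intensity was at least 50 on both arrays, and probes of the same name were averaged on log2. Where a single array reached the floor, the brighter value was set against the lowest normalized intensity among mouse probes above the floor on the dim array, and the result is given as "at least N-fold". A miRNA was counted as higher or lower at 2-fold. With 1 array per group no p-value, SD or SE was computed across samples; the number of arrays limits the precision.

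Before the data were examined, 16 miRNA lists were fixed: myeloid, inflammatory, let-7, miR-15/16, miR-17~92 with its paralogs, miR-23/27/24, miR-29, miR-30, p53-responsive, hypoxia, lymphoid, erythroid and megakaryocyte, epithelial, mesenchymal, Dlk1-Dio3 and tissue-restricted. A list with at least 3 measured members is described by its median log2 ratio and by the percentile of that median among 10000 random lists of the same size matched on level in 10 bins. Named miRNAs followed a rule fixed at the same time. In each comparison it took up to 10 in each direction past 2-fold among those above the lowest 25% of levels, the 5 widest bounds each way, and list members with the largest difference in either direction or the highest level. It added miR-22, miR-155, miR-16 and miR-503 throughout and the 5 highest levels of each array. miRNAs named outside that rule are marked as such only in part. Unmarked ones include miR-142-3p and miR-223 for ID8 over control, and miR-103, miR-711 and miR-801 for CT-26 over control.

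The shared control was treated by simulating 1000 sets of 3 unchanged arrays, with a log2 SD of 0.398 per array taken from the ID8 over CT-26 ratios. The calculation of ratios, bounds and counts was tested on simulated arrays of 579 probes with a noise SD of 0.2 on log2. For the simulated ID8 over control comparison, 15 of 15 probes made 4-fold higher and 14 of 15 made 4-fold lower were recovered, and 0 others were called. The changed probes averaged at least 100 units, and the noise was below the 0.398 taken from the arrays. That run checks the calculation only, and the share of false calls in the data was not measured. Alternatives were other normalizations between arrays, floors of 100, 200, none and the 95th percentile of viral probes, an offset of 50, normexp background correction from limma, thresholds of 1.5-fold and 4-fold, all probes, and single probes. Scaling to the U6-snRNA-2 probe and to the SNORD3@ probe was added after seeing the data. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, matplotlib 3.10.9, R 4.3.3 and limma 3.58.1 were used. Probes with no name entered only counts of probes above the floor, counts of 2-fold ratios of their own and the alternative over all probes.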

Results

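MicroRNA levels were measured in mouse bone marrow-derived dendritic cells (BMDCs), antigen-presenting cells grown from marrow, with 3 single-colour arrays of locked nucleic acid capture probes. The control group was BMDCs with no tumour cells named in the labels. Its plates, serum and time in culture are not given, so ratios to it may also reflect culture conditions. The other groups were BMDCs kept for 24 h in transwell plates, in medium with 3% serum, beside ID8 cells, a mouse ovarian tumour line, or beside CT-26 cells, a mouse colon carcinoma line. Each group had 1 array, so there are no replicates, no test was run, and every ratio describes a pair of arrays. Of 579 probes with a mouse miRNA name, 175 on the control array, 192 on the ID8 array and 178 on the CT-26 array had a background-subtracted intensity of at least 50, the floor used throughout. The median local background was 57.75, 49.5 and 48.25 intensity units on those arrays, and the brightest of 21 empty spots reached 6, 1.75 and 2.25 units above it. The floor was also reached by 6, 6 and 5 of 10 viral probes and by 183, 185 and 164 of 660 probes with no name. It was reached by 0 of 78 spike-in probes and, on the control and CT-26 arrays, by 1 of 8 negative probes. A mouse probe above the floor thus gave more signal than empty spots. That alone does not show that it bound the miRNA it is named for.

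The first comparison asked which miRNAs differ between BMDCs exposed to ID8 ovarian tumour cells and control BMDCs. miR-22, which is abundant in myeloid cells, was 4.88-fold higher in the ID8 co-culture, miR-146a, which is induced by NF-kB signalling, 4.78-fold higher, and miR-21, which is abundant in activated immune cells and many tumours, 4.27-fold higher. miR-155, made from the Bic transcript after Toll-like receptor stimulation, was at least 4.20-fold higher, since its probe read 49.5 on the control array, just under the floor, and 258.5 on the ID8 array. miR-17 and miR-20a, products of the growth-promoting miR-17~92 cluster, were 2.46-fold and 2.45-fold higher, and miR-16, which restrains Bcl2 and cell cycle genes, was 2.23-fold higher. When the arrays were instead scaled to the U6 probe, the medians of the myeloid and inflammatory lists were -0.10 and -0.85.

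Among 165 mouse miRNAs above the floor on both arrays, 8 were at least 2-fold higher and 5 at least 2-fold lower in the ID8 co-culture. The higher ones also included miR-142-5p, from a precursor made in blood cells, at 2.25-fold, and let-7d at 2.20-fold. The lower ones were miR-24-2* (4.14-fold), miR-433* (3.12-fold), miR-673-3p (2.53-fold), miR-138 (2.47-fold) and miR-708 (2.42-fold, named here after its value was seen). miR-138 has a pair of probes, and only 1 of them was above the floor. A further 3 miRNAs were above the floor on the ID8 array and not on the control array and at least 2-fold higher, namely miR-155, miR-674 (at least 2.32-fold) and miR-146b (at least 2.06-fold). Another 3 were above it on the control array and not on the ID8 array, and miR-28*, miR-370 and miR-486 were at least 4.40-fold, 2.73-fold and 2.41-fold lower in the ID8 co-culture. miR-503 had a log2 ratio of 0.70. Several leading miRNAs were close to the floor on the control array, where miR-146a read 54.25 units, miR-17 56 units and miR-21 65.5 units, and at a floor of 100 the counts were 4 higher and 3 lower, against 45 and 50 with no floor.

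Of 13 miRNAs listed beforehand as abundant in myeloid cells, 7 were measured on both arrays, 4 of these were at least 2-fold higher, and the median log2 ratio was 1.17. This median lay at percentile 99.98 of 10000 random lists matched for size and level, and it was 1.08 with the 3 bounds included. Within the list, miR-142-3p had a log2 ratio of 0.13, miR-34a of 0.31 and miR-24 of -0.24. miR-223, a marker of granulocytes and macrophages, was at least 1.98-fold higher. The let-7 family had log2 ratios above 0 in all 6 measured members, 1 of them past 2-fold, with a median of 0.50 (percentile 99.25), although that median was -0.77 when the arrays were scaled to the U6 probe. The miR-17~92 list had 3 measured members, all above 0 and 2 past 2-fold, with a median of 1.29 (percentile 98.6), which was 0.58 with 2 bounds included and 0.02 under U6 scaling. Those past 2-fold were miR-17 and miR-20a, whose probes may share signal, and miR-17 read 56 units on the control array. By contrast miR-19a, miR-19b and miR-92a, of the same cluster, read at most 7.75 units on any array. The inflammatory list had a median of 0.42 (percentile 94.2), from 5 members that were all above 0, and it was 1.04 with bounds included and -0.85 under U6 scaling. Inside it, let-7e and miR-125a-5p, neighbours in the genome, had log2 ratios of 0.42 and 0.09, while miR-146a and miR-21 exceeded 2-fold.

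Other lists had medians near 0 in the ID8 co-culture. The median log2 ratio was 0.04 for the miR-15/16 family (percentile 39.1), 0.06 for p53-responsive miRNAs (percentile 63.2), 0.03 for the imprinted Dlk1-Dio3 cluster (percentile 37.7) and -0.08 for miRNAs restricted to other tissues (percentile 29.4). Under U6 scaling these medians were -1.23, -1.21, -1.23 and -1.35, in that order. In the miR-15/16 family, miR-16 stood at 1.16 and miR-497 at -0.45. The remaining lists had fewer than 3 measured members. miR-29a had a log2 ratio of 0.68, miR-30c of 0.05, miR-24 of the miR-23/27/24 clusters of -0.24 (miR-27a had a bound of 0.71), the epithelial miR-194 and miR-200b of -0.25 and -0.31 and the mesenchymal miR-214 of -0.35. Lymphocyte miRNAs were at or under the floor except miR-150, at 64.25 intensity units on the ID8 array, and among erythroid and megakaryocyte miRNAs miR-451 had a bound of 0.18 and miR-486 of -1.27. The hypoxia-responsive miR-210 was under the floor on all 3 arrays.

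The U6-snRNA-2 probe, a small nuclear RNA often used as a loading reference, was also higher in the ID8 co-culture, with a log2 ratio of 1.27, and the small nucleolar RNAs SNORD3@ and SNORD2 had log2 ratios of 0.33 and 0.23. Scaled to U6-snRNA-2, 1 miRNA was at least 2-fold higher and 117 lower, and the myeloid list had a median of -0.10, with miR-142-5p at -0.10 and miR-16 at -0.11. Scaled to SNORD3@, 3 were higher and 10 lower.

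**Figure D1:**
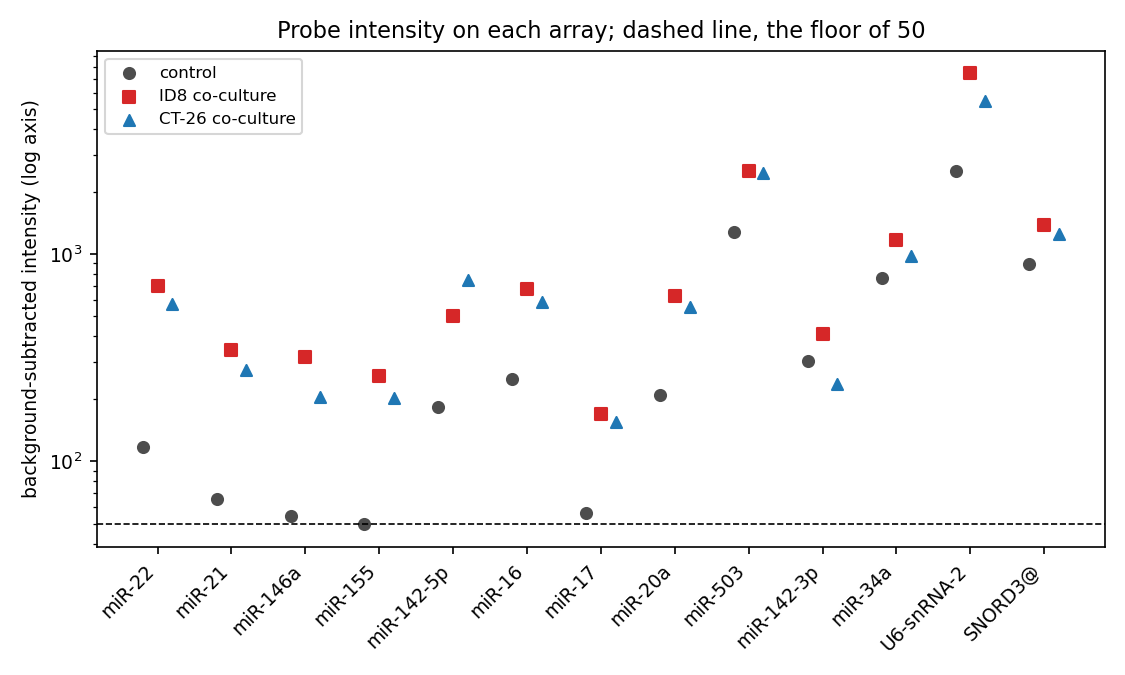
Background-subtracted intensity (log axis) of 11 miRNA probes and 2 small RNA reference probes on the control, ID8 and CT-26 arrays, with 1 point per array and the floor of 50 as a dashed line. miR-155 read 49.5 on the control array, 258.5 on the ID8 array and 201.5 on the CT-26 array, and U6-snRNA-2 read 2522, 7445 and 5464.5 units.

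The same question was asked of BMDCs exposed to CT-26 colon tumour cells. The myeloid miRNAs miR-22, miR-21 and miR-142-5p were 4.72-fold, 4.06-fold and 4.02-fold higher than in control BMDCs, and miR-146a was 3.66-fold higher. miR-155 was at least 3.89-fold higher, with 201.5 intensity units on the CT-26 array. miR-17, miR-20a and miR-16 were 2.66-fold, 2.58-fold and 2.30-fold higher. miR-574-5p was 8.36-fold lower, and the opposite arm of its precursor, miR-574-3p, was 2.22-fold lower.

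Among 158 mouse miRNAs above the floor on both arrays, 21 were at least 2-fold higher and 11 at least 2-fold lower. The higher ones included miR-194, an intestinal and liver miRNA (3.50-fold), miR-129-5p (3.48-fold), miR-1, a muscle miRNA (3.41-fold), and miR-290-5p of embryonic stem cells (log2 ratio 1.35). miR-194 read 51.75 units on the control array, close to the floor. Of the 19 miRNAs listed as restricted to other tissues, 14 were under the floor on both arrays. Whether the miR-1 and miR-290-5p probes bound other RNA was not tested. miR-21* (log2 ratio 1.58), miR-103 (1.44), miR-711 (1.3), miR-675-5p of the H19 transcript (1.27), miR-695 (1.08) and miR-801 (1.02) were higher as well. The lower ones included miR-24-2* (5.91-fold), miR-138 and miR-433* (both 3.38-fold) and miR-483, which lies within Igf2 (3.26-fold). miR-466b-5p had a log2 ratio of -1.57, miR-678 of -1.52, miR-207 of -1.20 and miR-693-5p of -1.01. miRNAs above the floor on the CT-26 array and not on the control array and at least 2-fold higher numbered 6, among them miR-223 (at least 2.42-fold), miR-674 (at least 2.33-fold), miR-27a (at least 2.29-fold), let-7i (at least 2.10-fold) and miR-146b (at least 2.01-fold). The 5 bounds in the other direction were miR-28* (at least 3.70-fold lower), miR-206, a muscle miRNA (at least 2.5-fold), miR-708 (at least 2.46-fold), miR-370 (at least 2.30-fold) and miR-486 (at least 2.03-fold). miR-503 had a log2 ratio of 0.91. At a floor of 100 the counts were 13 higher and 6 lower, and with no floor 62 and 71.

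The myeloid list had a median log2 ratio of 1.94 over 6 measured members, above every random list (percentile 100), which was 1.57 with bounds included and 0.87 under U6 scaling. In it miR-142-3p had a log2 ratio of -0.41, and miR-24, under the floor on the CT-26 array, a bound of -0.20. The miR-17~92 list had a median of 1.37 over 3 members (percentile 94.3), which was 0.91 with bounds included and 0.30 under U6 scaling. Again miR-17 and miR-20a, whose probes may share signal, were the members past 2-fold. The inflammatory list had a median of 0.37 over 5 members (percentile 74.3), which was 0.69 with bounds included and -0.70 under U6 scaling. The let-7 family had log2 ratios above 0 in all 6 measured members, 0 of them past 2-fold, with a median of 0.52 (percentile 84.0) that was -0.55 under U6 scaling. The median was 0.12 for the miR-15/16 family (percentile 62.7), 0.30 for p53-responsive miRNAs (percentile 56.1) and 0.02 for the Dlk1-Dio3 cluster (percentile 53.5). Under U6 scaling these were -0.95, -0.77 and -1.05, in that order. miRNAs restricted to other tissues had a median of 1.35 over 3 members (percentile 99.3), from miR-1, miR-290-5p and miR-122, and of -0.16 once the bounds of miR-206 and miR-293 were included and -0.85 with no floor.

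Lists with fewer than 3 measured members again have no median. miR-29a had a log2 ratio of 0.40, miR-30c of 0.33 and miR-214 of -0.35, and the epithelial miR-194 and miR-200b parted at 1.81 and -0.61. In the miR-23/27/24 clusters miR-27a and miR-24 had bounds of 1.19 and -0.20, and among erythroid and megakaryocyte miRNAs miR-451 and miR-486 had bounds of 0.20 and -1.02. U6-snRNA-2 had a log2 ratio of 1.07, SNORD3@ of 0.43 and SNORD2 of -0.47. Scaled to U6-snRNA-2, 1 miRNA was at least 2-fold higher and 83 lower, and scaled to SNORD3@ 10 were higher and 31 lower.

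**Figure D2:**
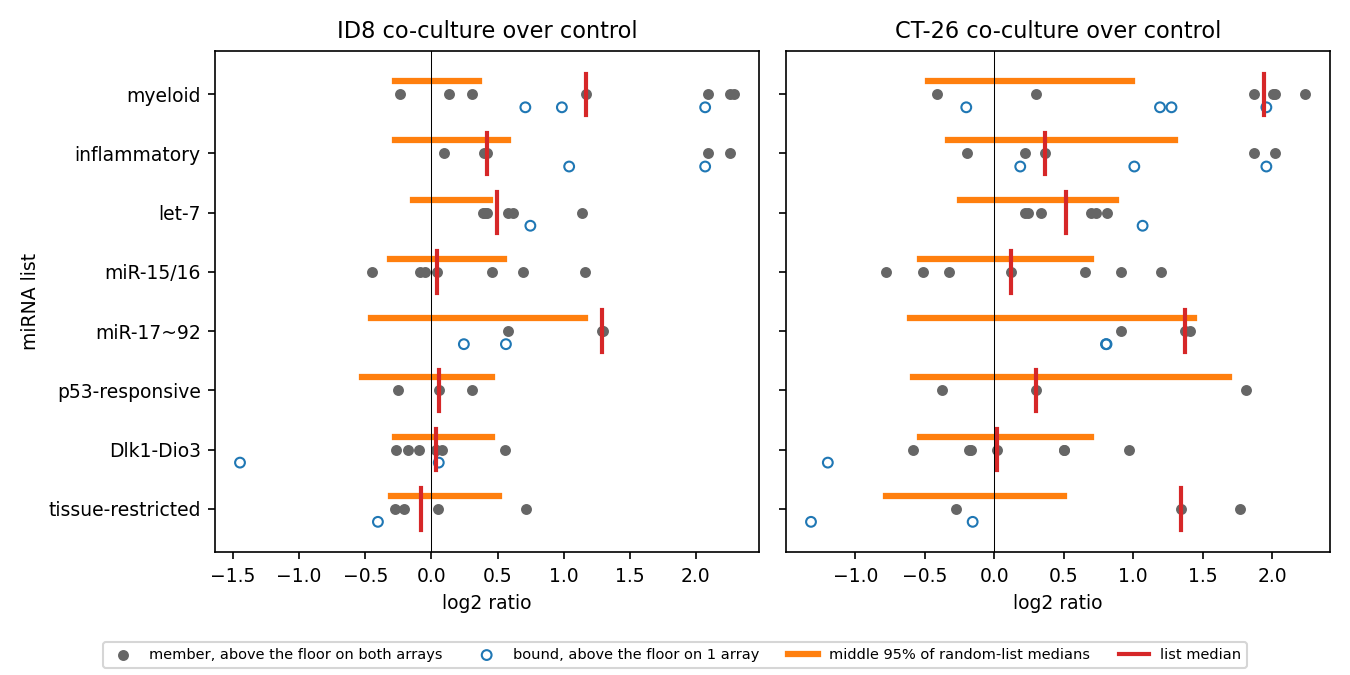
Log2 ratios of the members of 8 miRNA lists (rows) in the ID8 co-culture over control and the CT-26 co-culture over control, 1 array per group. Grey points are members above the floor on both arrays, open circles are bounds, red lines are list medians and orange bars span the middle 95% of random-list medians; the myeloid medians were 1.17 and 1.94, and they were -0.10 and 0.87 when scaled to the U6 probe.

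Setting the ID8 co-culture directly over the CT-26 co-culture asked how the response of BMDCs depends on the tumour line. Among the leading myeloid and inflammatory miRNAs, the log2 ratio was 0.05 for miR-22, 0.07 for miR-21, 0.11 for miR-155, 0.38 for miR-146a and -0.83 for miR-142-5p. It was -0.04 for miR-16 and -0.22 for miR-503. The widest differences lay elsewhere. miR-574-5p was 4.87-fold higher beside ID8 cells, and miR-483, miR-678 and miR-466b-5p had log2 ratios of 1.58, 1.57 and 1.41. miR-194 was 4.17-fold lower beside ID8 cells, and miR-129-5p and miR-103 were both 2.71-fold lower. The miR-194 ratio rests on a reading close to the floor, 53.25 units on the ID8 array against 187 on the CT-26 array.

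In all, 4 miRNAs were at least 2-fold higher and 11 at least 2-fold lower beside ID8 cells, among 175 above the floor on both arrays. miR-107, which differs from miR-103 by a single base, so that their probes may share signal, was 2.57-fold lower, and it is named for that likeness after its value was seen. The others on the lower side were miR-675-5p (log2 ratio -1.36), miR-21* (-1.30), miR-290-5p (-1.30), miR-711 (-1.29), miR-801 (-1.27), miR-337-3p (-1.06) and miR-1 (-1.06). miR-206 was at least 2.07-fold higher and miR-509-5p at least 2.31-fold lower beside ID8 cells. Without normalization, 7 miRNAs were higher and 9 lower, and with no floor 34 and 32.

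Most lists had medians near 0 between the co-cultures. The median log2 ratio was 0.05 for myeloid miRNAs (percentile 67.1), 0.09 for inflammatory miRNAs (percentile 80.7; -0.11 under U6 scaling), 0.07 for let-7 (percentile 88.3), -0.04 for the miR-15/16 family (percentile 44.4) and 0.01 both for p53-responsive miRNAs (percentile 48.1) and for the Dlk1-Dio3 cluster (percentile 56.3). The miR-17~92 list had log2 ratios below 0 in all 5 measured members, 0 of them past 2-fold, with a median of -0.24 (percentile 15.1) that was 0.01 without normalization. miRNAs restricted to other tissues had a median of -1.06 over 3 members (percentile 2.62), of -0.49 with the bound of miR-206 and of -0.026 with no floor.

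**Figure D3:**
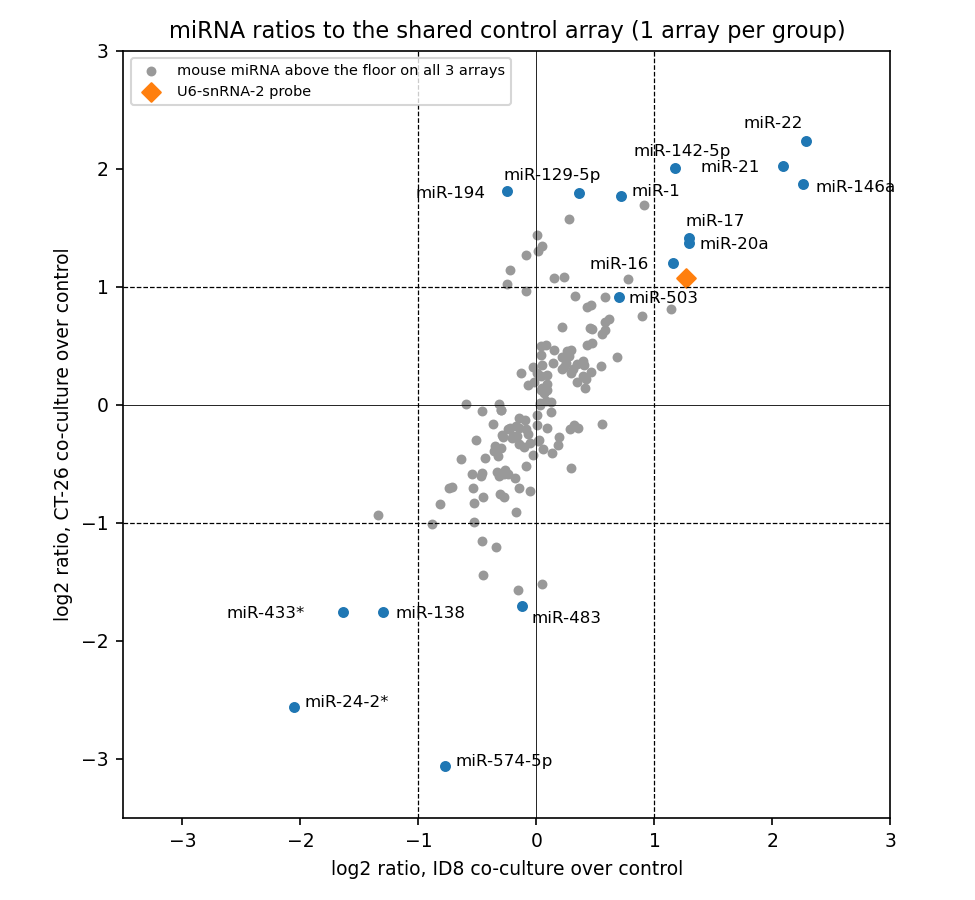
Log2 ratio of each mouse miRNA in the ID8 co-culture over control (x axis) and the CT-26 co-culture over control (y axis), for the 158 miRNAs above the floor on all 3 arrays, with dashed lines at 2-fold. miR-22, miR-21, miR-146a, miR-142-5p, miR-16, miR-17 and miR-20a lie past 2-fold on both axes, as does the U6-snRNA-2 probe (orange), whose ratios of 1.27 and 1.07 would be 0 under U6 scaling.

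Whether both tumour lines went with the same miRNAs was asked by the overlap of the 2 comparisons. miR-22, miR-21, miR-146a, miR-142-5p, miR-16, miR-17 and miR-20a were at least 2-fold higher in both co-cultures, and miR-24-2*, miR-433* and miR-138 at least 2-fold lower in both. Among miRNAs under the floor on 1 side, miR-155, miR-146b and miR-674 were at least 2-fold higher and miR-28*, miR-370 and miR-486 at least 2-fold lower in both. miR-708 was at least 2-fold lower in both as well, measured for ID8 and as a bound for CT-26. No miRNA passed 2-fold in opposite directions.

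Over the 158 miRNAs measured on all 3 arrays, 7 were higher in both, where independent lists of those sizes would share 1.06 and simulated unchanged arrays with a shared control 1.32. The 3 that were lower in both compare with 0.28 and 1.31. At a floor of 100 the shared counts were 4 higher and 0 lower, and with no floor 36 and 37. The ratios had the same sign for 131 miRNAs (82.9%), against 66.6% in the simulation. Across miRNAs, which are not independent replicates, Pearson's r was 0.75 and Spearman's rho 0.75, with a simulated r of 0.49, and the covariance was 0.367 against a simulated 0.157. The control array cannot be split, so part of the excess may come from it, and scaled to U6-snRNA-2 the shared counts were 1 higher and 78 lower. The simulation took its spread from ID8 over CT-26 and so leaves out the noise of the control array itself. Empty spots had an SD of 2.47 units on the control array, 0.84 on the ID8 array and 0.76 on the CT-26 array. A noisier control would raise the simulated values, which may therefore be too low. The same spread also holds any true difference between the co-cultures, which would make the simulated counts and covariance too high. A single SD was used for all probes, although probes near the floor, such as miR-146a, miR-17 and miR-21 on the control array, may vary more. The simulated values are thus a rough guide and may err in either direction.

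Probes without a mouse miRNA name gave signal as well. Of 10 probes for miRNAs of murine gammaherpesvirus, 6 were above the floor on the control array, 6 on the ID8 array and 5 on the CT-26 array, and mghv-miR-M1-4 had normalized levels of 10.2, 12.7 and 13.1. Of 660 probes with no name in the table, 183, 185 and 164 were above the floor. The mouse probes among the 5 highest levels on every array were miR-551b, with normalized levels of 79.9, 45.3 and 44.5 on the control, ID8 and CT-26 arrays, miR-693-5p (78.8, 42.8 and 39.1) and miR-138*. miR-483 (41.2, 37.7 and 12.6) was among them on the control and ID8 arrays, miR-667 on the control array, miR-883a-5p on both co-culture arrays and miR-503* on the CT-26 array. Levels of different probes cannot be ranked as amounts of miRNA, since probes differ in affinity. All 78 spike-in probes lay under the floor, so no added RNA fixes the scale between arrays.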

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

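All tests of explanations in this part were chosen after the results were seen. For 6 miRNAs the co-cultures lay on opposite sides of the control array and at least 2-fold apart, and the difference was not tested. The log2 ratio of ID8 over CT-26 was -2.06 for miR-194, -1.36 for miR-107, -1.06 for miR-337-3p, -1.36 for miR-675-5p, 1.57 for miR-678 and -1.27 for miR-801. In the same order, ID8 over control gave -0.25, -0.22, -0.09, -0.09, 0.05 and -0.25, and CT-26 over control 1.81, 1.14, 0.97, 1.27, -1.52 and 1.02. The ID8 ratios are smaller than the 0.29 by which no normalization shifted that comparison. ID8 thus lay near the control, and the differences come mainly from the CT-26 array. Among probes with no name in the table, which the comparisons do not use, 4 were at least 2-fold higher and 3 lower on the ID8 array than on the control array, with 0 bounds higher and 4 lower, and 10 were higher and 8 lower on the CT-26 array, with 1 bound higher and 4 lower. Among viral probes above the floor on both arrays of a pair, 4 had a higher and 2 a lower normalized level on the ID8 array than on the control array, and 4 a higher and 1 a lower level on the CT-26 array.

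The medians of the myeloid, let-7 and miR-17~92 lists and the log2 ratio of the U6-snRNA-2 probe were above 0 for both co-culture arrays over the control array. With bounds left out, the 5 other lists with a median lay lower for ID8, though 4 of them were above 0 on both arrays as well. These were the inflammatory (0.42 and 0.37), miR-15/16 (0.04 and 0.12), p53-responsive (0.06 and 0.30) and Dlk1-Dio3 lists (0.03 and 0.02). The tissue-restricted list had -0.08 and 1.35. With bounds included, the inflammatory median for ID8 was 1.04, above those of let-7 and miR-17~92 (both 0.58), so that list lies outside the pattern only without bounds. A shortfall of cell RNA on the control array of the size U6 shows would move let-7 and U6 alike, if their probes read cell RNA alone. Yet the let-7 median minus the U6 log2 ratio was -0.77 for ID8 and -0.55 for CT-26, where the let-7 members had SDs of 0.28 and 0.27. The scaling constant of each array cancels in that difference. A shortfall shared by all mouse probes is removed by the constant and cannot be seen in the ratios. U6 rests on 1 probe here. A shortfall of a size not known, acting alike on all lists, was set against those 5 lists. For ID8, 3 of the 5 had medians below the let-7 median by more than the larger SD of members, with bounds left out and included. They were p53-responsive (0.44 below, SD 0.28), Dlk1-Dio3 (0.46, SD 0.28, and 0.546 against 0.543 with bounds) and tissue-restricted miRNAs (0.58, SD 0.45). This cannot decide the question for ID8, because the lists were grouped after their medians were seen. Moreover, 24 of 33 Dlk1-Dio3 and 14 of 19 tissue-restricted members were under the floor on both arrays, so few members carry those medians. The p53-responsive and tissue-restricted lists have 3 and 4 measured members. For CT-26, 0 of the 5 lists did. There the myeloid median exceeded the let-7 median by 1.42 among measured members, with an SD of 1.11, but by 0.87 to 1.31 over the range that the bounds allow, which spans that SD, so such a shortfall and an effect of co-culture cannot be told apart for CT-26. Among other small RNA probes, SNORD3@ had log2 ratios of 0.33 and 0.43 and SNORD2 of 0.23 and -0.47, and U6-snRNA-1 had 0.62 for ID8 and was under the floor on the CT-26 array; single probes have no spread here and were not used as a test. A shortfall acting unequally on the lists was not tested. It stays open for both arrays, as does the effect of the tumour cells, untested, because each group has 1 array and no spike-in probe was above the floor. The plates, serum and time of the control culture are not given either. A difference in culture conditions therefore cannot be told apart from an effect of the tumour cells in any ratio to the control.

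The 40 Hy3 marker spots had near-identical raw intensities on the control and ID8 arrays: all 40 differed by under 0.2%, by 1.75 to 4.75 units on spots of 3027 to 5812 units. Hy3 spots that vary little between any arrays are argued against, since the CT-26 and control arrays differed by a median of 7.29%, and so is the whole ID8 array repeating the control array, since 0 of 136 other bright probes agreed within 0.2%. Hy3 values carried over from 1 array to the other remain a candidate explanation, as the difference had an SD of 0.592 units. No biological explanation was tested.

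Probes of viral miRNAs gave signal although the labels name no virus. Binding of labelled RNA to capture probes of any sequence is argued against, as 1 of the 78 spike-in and 8 negative probes was above the floor on any array, a negative probe that read 59 units on the control array and 52 on the CT-26 array. A floor below the array's own background is argued against too, since the brightest empty spot read 6 units. Binding of mouse RNA to single probes of like sequence may account for the 5 viral probes above the floor on all 3 arrays, but viral RNA in the cultures would light the same probes, so these cannot be told apart. No biological explanation was tested.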

How the results depend on the processing

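Scaling to U6-snRNA-2 and to SNORD3@ was chosen after seeing the data; the other alternatives were fixed beforehand. Counts are given as higher and lower at 2-fold for ID8 over control, CT-26 over control and ID8 over CT-26, then as shared by both co-cultures; the values used in the report are 8 and 5, 21 and 11, 4 and 11, then 7 and 3. A list median counts as moved past the SD of its members. For the myeloid list that SD was 1.09 for ID8 and 1.11 for CT-26 over control. A drop smaller than that is not counted as moved. Counts stayed within 1.5 times and list medians within the SD of their members under quantile normalization, the median over all probes, the 75th percentile and the series matrix values, as did counts under single probes, where list medians were not run. Under quantile normalization 19 of the 21 higher calls of CT-26 over control remained. Where results moved, the cause was not tested, except that a higher floor leaves fewer probes and a threshold sets its own count. With 1 array per group, no replicate could be left out and no spread between samples exists; replicate spots were not used here, so their median was not run. Of the ratios of named miRNAs over all alternatives, 957 of 1217 stayed within 0.23 on log2, and 78 changed sign, of which 3 had been past 2-fold. The 0.23 is the mean SD of Hy3 spots within an array, which are bright marker spots. It serves as a yardstick only, since the error of a ratio was not measured. Of the list medians 56 of 265 changed sign, 8 of 24 under the 75th percentile and 5 of 24 under quantile normalization among them, so the direction of a median near 0 is not fixed. miR-146a, miR-17 and miR-21 read 54.25, 56 and 65.5 units on the control array, close to the floor, and their ratios depend on those readings.

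At a floor of 100 the counts were 4 and 3, 13 and 6, and 7 lower in ID8 over CT-26, with 4 and 0 shared. At 200 they were 2 and 1, 10 and 4, 2 and 7, with 2 and 0 shared; viral probes above that floor were 3 on each array and unnamed probes 102, 108 and 103. At the 95th percentile of viral probes they were 0 and 0, 0 and 2, 1 and 0, with 0 and 0 shared. With no floor they were 45 and 50, 62 and 71, 34 and 32, with 36 and 37 shared; the miR-17~92 median was 0.51 for ID8 and 0.87 for CT-26, and the tissue-restricted median was -0.85 for CT-26 over control, the reverse of 1.35, and -0.026 for ID8 over CT-26. At 1.5-fold the counts were 15 and 12, 36 and 29, 11 and 18, with 14 and 9 shared; at 4-fold 3 and 1, 3 and 2, 1 and 1, with 2 and 1 shared. Over all probes they were 13 and 8, 32 and 19, and 19 lower in ID8 over CT-26, with 11 and 5 shared.

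With an offset of 50, 5 miRNAs were higher in ID8 over control, and the miR-17~92 median was 0.79 for ID8 and 0.90 for CT-26. With normexp, 5 were higher in ID8 over control and 7 lower in ID8 over CT-26, and that median was 0.71 and 0.82. No normalization shifted the median of all miRNAs by 0.29 in ID8 over control and by 0.25 in ID8 over CT-26, quantile normalization by -0.11 in ID8 over control, and the 75th percentile by -0.12 and -0.14. Without normalization, 7 were higher in ID8 over CT-26; for ID8 over control the medians were 0.79 (let-7), 0.35 (p53-responsive) and 0.33 (Dlk1-Dio3), and for ID8 over CT-26 0.34 (inflammatory), 0.32 (let-7) and 0.00795 (miR-17~92).

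Scaling to U6-snRNA-2 shifted the median of all miRNAs by -1.27, -1.07 and -0.20, and gave 1 and 117 for ID8 over control and 1 and 83 for CT-26 over control, with 1 and 78 shared. For ID8 over control the medians, all but that of miR-17~92 below 0, were -0.10 (myeloid), -0.85 (inflammatory), -0.77 (let-7), -1.23 (miR-15/16), 0.0213 (miR-17~92), -1.21 (p53-responsive), -1.23 (Dlk1-Dio3) and -1.35 (tissue-restricted). For CT-26 over control they were -0.70 (inflammatory), -0.55 (let-7), -0.95 (miR-15/16), 0.30 (miR-17~92) and -1.05 (Dlk1-Dio3), and, within the SD, 0.87 (myeloid), -0.77 (p53-responsive, from 0.30) and 0.27 (tissue-restricted, from 1.35). For ID8 over CT-26 they were -0.11 (inflammatory) and -0.44 (miR-17~92), and, within the SD, -0.15 (myeloid), -0.13 (let-7), -0.24 (miR-15/16), -0.19 (p53-responsive), -0.19 (Dlk1-Dio3) and -1.25 (tissue-restricted). In all, 16 of 24 medians changed sign under this scaling. Of 104 ratios of named miRNAs 23 changed sign, among them miR-503 in both co-cultures; those past 2-fold before were miR-142-5p at -0.10 and miR-16 at -0.11 in ID8 over control, and miR-801 at -0.0463 in CT-26 over control. Scaling to SNORD3@ shifted the median by -0.33 and -0.43 against the control, and gave 3 and 10, and 10 and 31, with 3 and 9 shared; the medians were 0.17 (let-7), -0.27 (p53-responsive) and -0.30 (Dlk1-Dio3) for ID8, and 0.0868 (let-7) and 0.94 (miR-17~92) for CT-26.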

Other observations

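miRNAs made from the same precursor or from neighbouring genes did not always have like ratios. The arms of the miR-142 precursor parted: miR-142-5p had log2 ratios of 1.17 for ID8 over control and 2.01 for CT-26 over control, and miR-142-3p of 0.13 and -0.41. Both arms of miR-574 were lower in the CT-26 co-culture, at -3.06 for miR-574-5p and -1.15 for miR-574-3p. miR-21* had log2 ratios of 0.28 and 1.58, where miR-21 had 2.09 and 2.02. miR-24-2*, at -2.05 and -2.56, shares a precursor with miR-24, at -0.24 in ID8 over control, and lies beside miR-27a, which was at least 1.64-fold higher for ID8 and 2.29-fold higher for CT-26.

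In the cluster of Mir322, Mir503 and Mir351, miR-503 had log2 ratios of 0.70 and 0.91, miR-351 of 0.35 and 0.19, and miR-322 of -0.09 and -0.52. miR-15a and miR-15b, which each lie beside a miR-16 gene, had log2 ratios of 0.46 and -0.05 for ID8 and of 0.65 and -0.33 for CT-26, with miR-16 at 1.16 and 1.20. miR-17 and miR-20a, neighbours in their cluster, lay close together at 1.3 and 1.29 for ID8 and 1.41 and 1.37 for CT-26, though their probes may share signal. These miRNAs were set side by side after their values were seen, and no test was run on them.

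The 2 U6 probes did not match: U6-snRNA-1 read 61.5, 116 and 36.5 units on the control, ID8 and CT-26 arrays, and U6-snRNA-2 read 2522, 7445 and 5464.5.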
